A study of Mus musculus with 28 samples.

How the data were processed

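The samples were 28 bulk RNA-seq libraries from B cell subsets that had been sorted by flow cytometry from the spleens of female mice. Per the labels' protocols, RNA was purified with a QIAGEN micro column kit and libraries were made with a Takara SMARTer Pico kit, which is built for small or degraded total RNA inputs. Per the submitters' processing notes, the authors used FastQC, STAR 2.7.1a and featureCounts. The genome build, the strand setting and any use of molecular identifiers are not given in the sources used here. The deposited values are whole-number counts per feature, not normalized, with 1 table per library, as the files themselves show. Each table lists the same 40303 feature IDs in the same order, and 8156 of them had no count in any library. Without a stated strand setting, reads of overlapping features on opposite strands cannot be assigned with certainty, and the same holds for near-identical copies.

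All IDs carry the prefix MGP_BALBcJ_G. The files do not pair these IDs with gene names, and 0 of the 40303 IDs were found in the mouse annotation tables used here. No gene name, chromosome, biotype or length was therefore given to any feature. The level of Xist, the X-linked genes, immunoglobulin and mitochondrial shares, GC content, and the 24 gene lists chosen for B cell states, other cell types and RNA quality had been planned and are not reported, because 0 IDs could be matched to a listed gene. The targeted gene was therefore not used to check the library labels. At most 2 risen and 2 fallen features are given by ID.

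Groups were taken from the sample labels, which call the libraries biological replicates. A number in the name of each deposited table recurs across the sorted subsets and was read as the animal, which gives 12 animals. Counts within every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom from 3.73 to 205.5 over features with a summed count of at least 20, so no library was treated as a repeat of another. Library totals ran from 2133489 to 23866710 counts. CPM values are given as mean ± SD on plain library totals. Intervals on shares are 95% Wilson intervals and cover counting error only, since reads copied by PCR are not independent molecules.

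Differences were computed from the deposited counts with R 4.3.3 and edgeR 4.0.16. Features were filtered with filterByExpr, library sizes were scaled by TMM, dispersions were estimated with robust settings, and the two-sided quasi-likelihood test was used with Benjamini-Hochberg adjustment. A feature was called changed at an adjusted p under 0.05, and all adjusted p-values come from this test unless another tool is named. Each subset was fitted alone, the WT libraries of the subsets were fitted together to compare subsets, and all 28 libraries were fitted together to test whether the cKO effect differed between subsets. These designs, the alternatives and the rule for single features were fixed before the data were examined. That rule took, per comparison and direction, the 10 largest fold changes among called features with a mean of at least 5 CPM in the higher group and no overlap between the groups. One low-abundance feature described without an ID is within it for ABC and outside it for the other comparisons, where it was chosen after its values were seen. Log2 CPM used a prior count of 2.

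The pipeline was tested on simulated data drawn from the real means, library sizes and spreads, with 50 features changed at each of 4 sizes. Changed features had a mean of at least 5 CPM over the groups, and features were drawn independently. Recovery of scarcer features, and the effect of libraries that deviate as a whole, were therefore not measured. At 2-fold, edgeR recovered 88% in CD23+ cKO low against WT, 90% in CD23+ cKO high against WT, 88% in CD23+ cKO high against cKO low, 68% in ABC and 20% in LLPC. At 4-fold it recovered 98%, 100%, 98%, 94% and 88%. For the difference of the effect between subsets, the 2-fold recovery was 42% for ABC minus CD23+, 20% for LLPC minus CD23+ and 38% for LLPC minus ABC.

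Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), DESeq2 size factors, no filter, a stricter filter of at least 1 CPM, a log2 fold change of at least 1, all libraries in 1 fit, each library left out in turn, and a block by replicate number or by animal. Leaving out the 10 most abundant features before scaling, a covariate for the series of animal numbers, and leaving out both CD23+ libraries of the higher number series were added after the data had been seen. Libraries of the same animal deviated together across subsets, with a median correlation across features of 0.09 for CD23+ and ABC, 0.09 for CD23+ and LLPC and 0.03 for ABC and LLPC, against -0.02, -0.03 and -0.02 for different animals. The pairing across subsets comes from the animal numbers, so comparisons between subsets are also given with the animal as a block where that moves the count of calls. The regrouping of the animals behind the correlation of ABC and CD23+ fold changes was also chosen after the data had been seen.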

Results

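RNA was measured in 3 B cell subsets sorted from the spleens of female mice that carried either an intact Xist gene (WT) or a conditional deletion of Xist in B cells (cKO). Xist is the noncoding RNA that coats and silences the inactive X chromosome. The subsets were CD23+ B cells, a surface phenotype of follicular B cells, CD11c+ age-associated B cells (ABC), and B220- CD138+ long-lived plasma cells (LLPC). The cKO animals were labelled by disease state as high dsDNA or low dsDNA, the former being the animals with lupus-like disease, and all WT animals had the low dsDNA label. There were 6 WT, 3 cKO low and 3 cKO high libraries of CD23+ cells, 4 WT and 3 cKO high libraries of ABC, and 6 WT and 3 cKO high libraries of LLPC. No cKO low library of ABC or LLPC was analysed here, so genotype and disease state changed together in those subsets.

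Totals ran from 6768292 to 23866710 counts in CD23+ WT, 7004444 to 10094498 in CD23+ cKO low, 7482127 to 7910726 in CD23+ cKO high and 4963298 to 9990545 in ABC WT. They ran from 2133489 to 9101435 in ABC cKO high, 4651060 to 10599602 in LLPC WT and 5570950 to 6510249 in LLPC cKO high. The same feature was the most abundant in all 28 libraries. Plasma cell libraries were concentrated on few features. The 10 leading features of each library took 43.1% ± 8.43 of counts in LLPC WT (SD, n = 6) and 49.5% ± 1.76 in LLPC cKO high (n = 3), against 14.1% ± 0.347 in CD23+ WT (n = 6) and 15.1% ± 2.79 in ABC WT (n = 4). The difference of 6.35 percentage points between LLPC cKO high and WT was within the spread of libraries (exact two-sided permutation test, p = 0.226, also 0.226 after adjustment over 3 composition measures).

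The WT libraries of the subsets show how far the sorted populations differed before any deletion. Plasma cells stood furthest from CD23+ cells. Of 13503 features tested, 9189 differed between WT LLPC and WT CD23+ cells, 4526 higher and 4663 lower in LLPC, with a median log2 fold change of 1.47 among the higher and -1.09 among the lower. ABC were nearer to CD23+ cells, with 3165 features changed, 1938 higher and 1227 lower in ABC, and a median log2 fold change of 1.74 among the higher. WT LLPC and WT ABC differed in 7144 features, 3286 higher and 3858 lower in LLPC. Rank correlations across features gave the same order of distance, although features are not independent replicates. The median Spearman rho between libraries was 0.94 for ABC and CD23+ cells, 0.85 for ABC and LLPC and 0.82 for CD23+ cells and LLPC, against 0.99, 0.98 and 0.95 within CD23+, ABC and LLPC.

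The comparison of CD23+ cKO low with CD23+ WT asked what the deletion changed in follicular-type B cells of animals without the disease label. Only 3 of 12542 tested features were called, and all fell. MGP_BALBcJ_G0007527 was at 1302 ± 138 CPM in WT (SD, n = 6) and 6.12 ± 0.719 CPM in cKO low (n = 3), which is 0.47% of the WT level (log2 fold change -7.71, SE 0.16, edgeR adjusted p = 1.43e-15). MGP_BALBcJ_G0031834 fell to 50.5% of its WT level, from 1120.0 ± 110 to 565.5 ± 33.9 CPM (log2 fold change -0.97, SE 0.105, adjusted p = 0.000177). The third was a low-abundance feature that fell from 4.87 ± 0.96 to 0.434 ± 0.175 CPM (log2 fold change -3.46, SE 0.369, adjusted p = 0.000177). At an unadjusted p under 0.05 there were 300 features, and DESeq2 called 5.

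**Figure D1:**
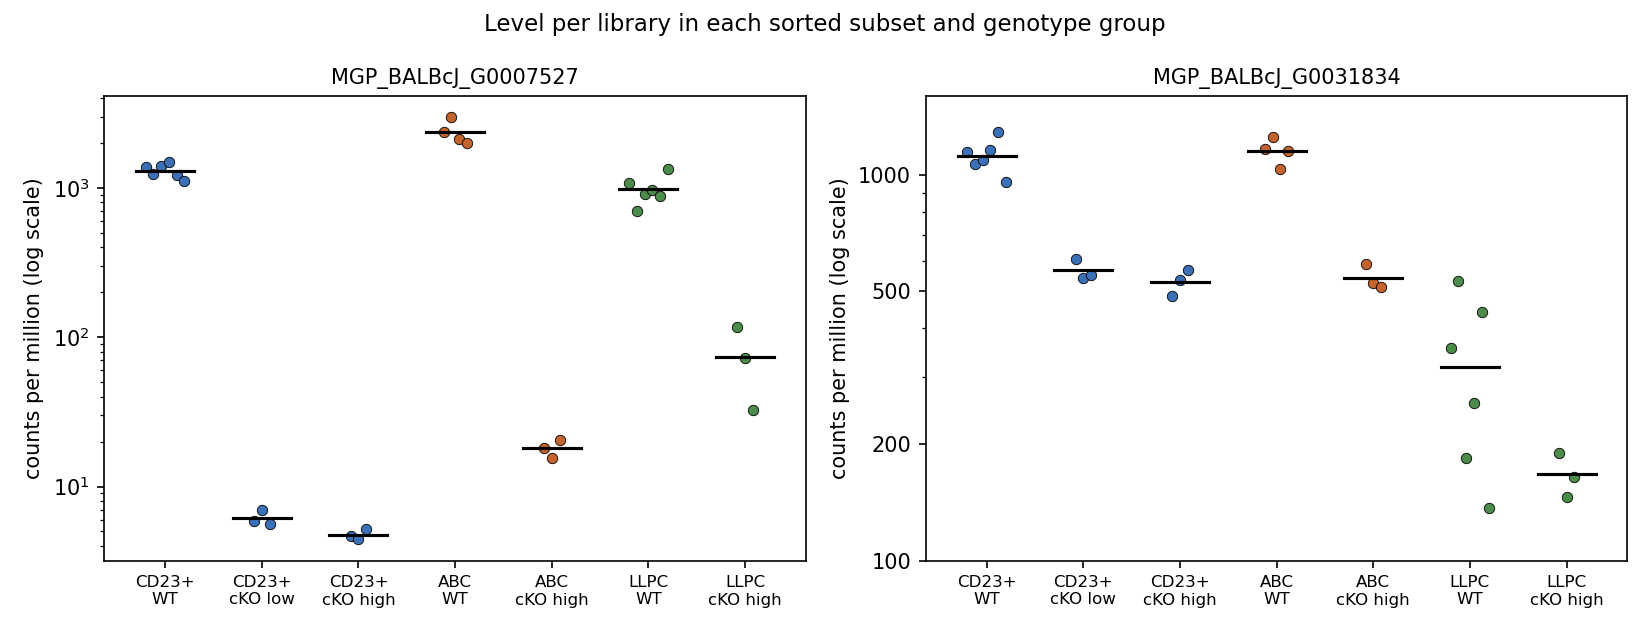
CPM on plain library totals for the 2 fallen features given by ID, on logarithmic vertical axes that differ between the panels. Each point is 1 library and each bar is the group mean: MGP_BALBcJ_G0007527 is at 1302 CPM in CD23+ WT and 4.76 CPM in CD23+ cKO high, but at 73.9 CPM in LLPC cKO high.

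The comparison of CD23+ cKO high with WT asked what accompanied the deletion in animals with the disease label. Here the changes were mostly increases. Of 12542 features 55 were called, 49 higher and 6 lower, and 43 of the higher were at least 2-fold up, with a median log2 fold change of 2.17 and quartiles of 1.42 and 2.54. The largest rise under the naming rule was that of MGP_BALBcJ_G0021447, from 1.08 ± 0.713 CPM in WT (SD, n = 6) to 10.8 ± 4.92 CPM in cKO high (n = 3), a log2 fold change of 3.26 (SE 0.423, adjusted p = 0.00144). The 2 fallen features given by ID were again low. MGP_BALBcJ_G0007527 was at 4.76 ± 0.407 CPM (log2 fold change -8.08, SE 0.165, adjusted p = 1.08e-15) and MGP_BALBcJ_G0031834 at 528.5 ± 40.5 CPM (log2 fold change -1.06, SE 0.105, adjusted p = 5.22e-05). The low-abundance feature was at 0.657 ± 0.148 CPM (log2 fold change -2.86, SE 0.349, adjusted p = 0.000534).

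The count of 55 was sensitive to 1 library, since 14 features were called without cKO high replicate 3, of which 10 were among the 55. It was 10 when all 28 libraries shared 1 estimate of the spread, and 138 with DESeq2. CD23+ WT replicate 6 and cKO low replicate 3 come from a separate series of animal numbers that holds no cKO high animal; without both, 69 features were called.

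**Figure D2:**
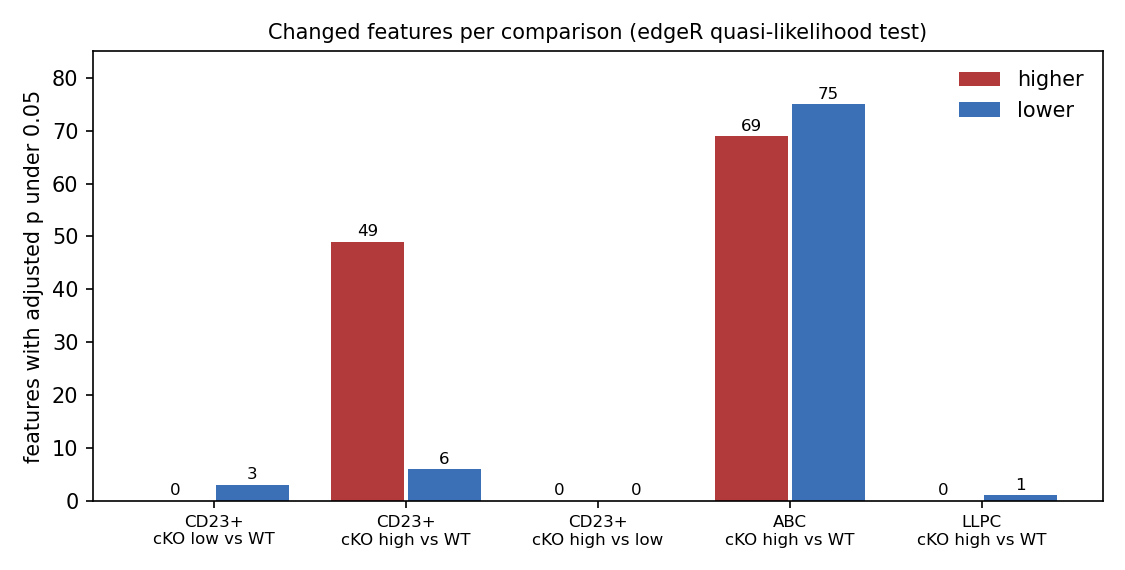
Number of features with an adjusted p under 0.05 in each comparison of genotype and disease groups, by direction. The bars are highest for ABC, with 69 higher and 75 lower, and for CD23+ cKO high against WT, with 49 higher and 6 lower.

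CD23+ cKO high and cKO low carry the same deletion and differ in disease label. No feature passed the edgeR test, the smallest adjusted p being 0.307, while 811 of 12542 features had an unadjusted p under 0.05, DESeq2 called 36 and limma 0. The 49 features that were higher in cKO high than in WT had a median log2 difference of 1.37 between cKO high and cKO low, and a median of 0.557 between cKO low and WT, but none of them was called in either comparison, and both values are too large because the features were chosen for being high in cKO high and low in these WT libraries. MGP_BALBcJ_G0021447 was at 1.70 ± 0.795 CPM in cKO low (n = 3), against 10.8 ± 4.92 in cKO high. MGP_BALBcJ_G0007527 did not differ detectably between these groups (log2 difference -0.36, SE 0.175, edgeR adjusted p = 0.714).

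**Figure D3:**
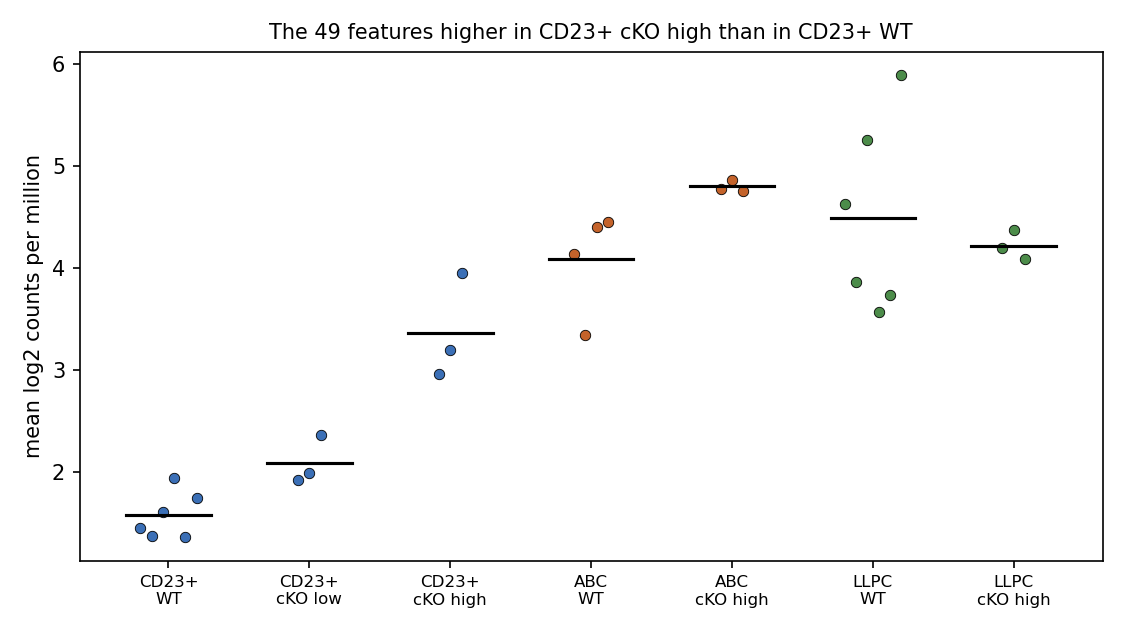
Mean log2 CPM of the 49 features that were higher in CD23+ cKO high than in WT, with 1 point per library. Group means run from 1.58 in CD23+ WT through 2.09 in cKO low to 3.37 in cKO high, where the first and last groups were used to choose the features, and lie at 4.09 in ABC WT and 4.5 in LLPC WT.

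Both comparisons with CD23+ WT use the same 6 WT libraries, which by itself makes fold changes correlate. The observed correlation across 12542 features was 0.15 with a covariance of 0.0189, and 58.0% of signs matched. In 50 simulations of unchanged groups the mean correlation was 0.31, the mean covariance 0.0225 and the mean share of matching signs 60.3%, so the covariance lay -0.00365 from the simulated mean. With the WT libraries divided 3 and 3 between the comparisons, the median correlation over 20 divisions was 0.03. The 3 features called in cKO low were also called lower in cKO high, where independent lists would share 0.00144 features.

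In ABC, cKO high against WT gave the widest response of the 3 subsets by count. Of 12714 features 144 were called, 69 higher and 75 lower, and 64 changed at least 2-fold. The higher features had a median log2 fold change of 0.9 and the lower ones of -0.95. MGP_BALBcJ_G0035851 rose from 4.25 ± 1.94 CPM in WT (SD, n = 4) to 41.3 ± 4.08 CPM in cKO high (n = 3), a log2 fold change of 3.33 (SE 0.278, adjusted p = 8.76e-05). It was second under the naming rule; the first rise reached 5.41 ± 1.14 CPM and kept its call under 10 of 16 alternatives. MGP_BALBcJ_G0007527 fell from 2361 ± 435 to 17.99 ± 2.46 CPM, 0.762% of WT (a 128.3-fold fall, SE 0.184 on the log2 scale, adjusted p = 6.2e-11), and MGP_BALBcJ_G0031834 from 1152 ± 90.8 to 541.6 ± 40.2 CPM, 47.0% of WT (log2 fold change -1.08, SE 0.104, adjusted p = 0.000186). The low-abundance feature fell from 17.5 ± 5.78 to 2.15 ± 0.619 CPM (log2 fold change -2.94, SE 0.346, adjusted p = 0.000776).

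The count of 144 moved with single libraries: 54 without WT replicate 1, 290 without WT replicate 2, and 41, 67 and 70 without cKO high replicates 1, 2 and 3, where replicate 2 was the shallowest library at 2133489 counts. DESeq2 called 442.

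The ABC and CD23+ comparisons share no libraries, but 3 cKO high and 4 WT animals gave both. Across 11820 features tested in both, the fold changes had a correlation of 0.36, and 59.5% of signs matched. Other groupings of the 7 animals, made alike in both subsets, gave correlations from 0.13 to 0.37, and 3 of 35 groupings, the real one included, reached the real correlation and 8 the share of signs, so neither of these exceeds what shared animals give. The covariance was 0.0643, above the highest other grouping at 0.047. The lists of lower features shared 4, against 0.0365 for independent lists, and those of higher features 1, against 0.236. Among these 4 were the 3 features also called lower in CD23+ cKO low, so most of this overlap was not particular to the disease label. Of the 49 features higher in CD23+ cKO high, 48 were on the higher side in ABC cKO high, with a median log2 difference of 0.615, and in LLPC 8 of 47 were, with a median of -0.924. The LLPC value depends on WT replicates 1, 3 and 6, since the mean log2 CPM of the 49 was 4.63 to 5.9 in these, 3.57 to 3.87 in the other WT libraries and 4.09 to 4.38 in cKO high. The mean log2 CPM of the 49 was 4.76 to 4.87 in ABC cKO high and 3.35 to 4.45 in ABC WT, groups that do not overlap, which chance gives in 5.71% of cases (exact two-sided permutation test, p = 0.0857, where 0.0286 is the smallest possible). In LLPC the means overlapped (exact two-sided permutation test, p = 0.679). None of the 14123 features differed in its effect between ABC and CD23+ cells by the edgeR test (smallest adjusted p = 0.0572), while 703 had an unadjusted p under 0.05, DESeq2 called 27, and 1 was called with the animal as a block. Up to 9 were called when 1 library was left out, the most without LLPC WT replicate 6.

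In LLPC, cKO high against WT changed a single feature of 11739. MGP_BALBcJ_G0007527 fell from 980.3 ± 211 CPM in WT (SD, n = 6) to 73.9 ± 42.1 CPM in cKO high (n = 3), with individual libraries from 32.6 to 117 CPM (log2 fold change -3.51, SE 0.369, adjusted p = 0.0234). An exact two-sided permutation test on its log2 CPM gave p = 0.0119, the smallest that 84 splits allow. MGP_BALBcJ_G0031834 was at 317.6 ± 152 CPM in WT and 167.3 ± 22.2 CPM in cKO high, a difference that did not pass the test (log2 fold change -0.77, SE 0.477, adjusted p = 0.751). The low-abundance feature was at 3.99 ± 1.49 CPM in WT and 1.41 ± 0.781 CPM in cKO high, 35.2% of WT (log2 fold change -1.23, SE 0.4, adjusted p = 0.751). At an unadjusted p under 0.05 there were 540 features, DESeq2 called 3 and limma 2. The call ended without any 1 of WT replicates 1 to 5 or cKO high replicate 2, each of which left 0 called features, although the log2 fold change of MGP_BALBcJ_G0007527 stayed between -3.95 and -3.17 over 18 alternatives. Replicates varied more here than elsewhere: the common biological coefficient of variation was 0.342 in LLPC, 0.216 in ABC and 0.164 in CD23+ cells.

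Whether the cKO high effect differed between plasma cells and the other subsets was tested directly. MGP_BALBcJ_G0007527 fell less in LLPC than in CD23+ cells, by a log2 difference of 4.55 (SE 0.323, adjusted p = 1.05e-09), and less in LLPC than in ABC, by 3.47 (SE 0.315, adjusted p = 2.8e-07). Both SEs come from 1 fit of all 28 libraries and lie below the 0.369 of the LLPC fall fitted alone. They and the adjusted p-values may therefore be too small. MGP_BALBcJ_G0007527 kept 7.54% of the WT level in LLPC cKO high, 0.365% in CD23+ cKO high and 0.762% in ABC cKO high. It was the only feature called for LLPC minus CD23+ (DESeq2 53, edgeR with the animal as a block 3), and 12 were called without LLPC WT replicate 4. For LLPC minus ABC there were 5 called features, all with a positive difference. The other 4 differed by 1.30 to 3.18 on the log2 scale, lay on the lower side in ABC cKO high and on the higher side in LLPC cKO high, and 3 of them were called in ABC. The count of 5 fell to 2 without any 1 of 10 libraries, ABC cKO high replicate 1 and LLPC cKO high replicate 2 among them, and reached 19 without LLPC cKO high replicate 3.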

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

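The tests of explanations in this part were chosen after the results were seen, whereas the counts over other splits of the samples were planned. In all, 29 checks for a library far from the rest were made, on several measures within the WT groups of 4 to 6 libraries. Of these checks 4 flagged a library, where chance gives 1.45 for independent checks. The checks were not independent, since linked measures flagged CD23+ WT replicate 6 more than once. The cKO groups were too small to be checked.

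MGP_BALBcJ_G0007527 kept more of its WT level in plasma cells than elsewhere, with a difference in log2 fold change of 4.55 for LLPC minus CD23+ and 3.47 for LLPC minus ABC. Carry-over of reads in proportion to the WT level of each subset, at the rate the ABC libraries allow, is argued against. The lowest LLPC cKO library kept 3.85 times the part of the WT level that the highest ABC cKO library kept. In plain CPM these libraries held 32.57 and 20.37, so the ratio rests in part on the lower WT mean in LLPC (980.3 against 2361 CPM in ABC). Carry-over from a pool shared by the subsets was not tested. What follows takes this feature as a transcript of the deleted locus, which could not be checked without gene names. On that assumption, cells or RNA with the undeleted locus in the plasma cell sort may account for the 7.54% that was left. Examples are long-lived cells formed before deletion or contamination with WT material, and these cannot be told apart. Such a share would weaken the fall of MGP_BALBcJ_G0031834 in LLPC by 0.114 on the log2 scale, but its log2 fold change there was -0.77 with an SE of 0.477, too wide to show it, and the low-abundance feature, which kept 35.2%, fell less than in CD23+ cells by 1.61 (adjusted p = 0.345) and less than in ABC by 1.69 (adjusted p = 0.252), which leaves it open. A slower loss of this RNA in plasma cells was not tested.

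Among the differences between subsets, 1 feature was called for LLPC minus CD23+ and 5 for LLPC minus ABC. When the 7 animals with all subsets were regrouped in 35 ways, 3 groupings gave at least 1 feature for LLPC minus CD23+ (highest other 97, so the animals hold a structure of their own) and 2 gave at least 5 for LLPC minus ABC (highest other 6). Chance cannot be excluded for either count. For ABC minus CD23+ all 35 groupings gave at least 0, which is the real count and the highest other.

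CD23+ WT replicate 6 had counts in 29517 features, against 16913 to 18879 in the other WT libraries of this subset. Depth is argued against as the reason, since thinned to 2000000 counts it still held 20304 features, against 13364 to 15227 in the other 27 libraries. Carry-over from those libraries is argued against too, because 5518 features had counts in this library and no other, while no other library had more than 98 such features. A few foreign transcripts do not account for it, as the 10 leading features took 1.46% (95% Wilson interval 1.28 to 1.66%) of those 15540 counts, which had a median of 2 per feature. Low-level background spread over the annotation, such as genomic DNA, stays open and was not tested, no feature lengths being used here, and no biological explanation was tested.

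In CD23+ WT replicate 3 the 10 leading features took 14.8% of counts (95% Wilson interval 14.7 to 14.8%), against 13.8 to 14.1% in the other WT libraries of this subset.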

How the results depend on the processing

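No alternative reversed the direction of a feature taken by the naming rule. The WT subset comparisons stayed within 1.5 times their counts under all alternatives tried. For the genotype comparisons the counts moved, in the order CD23+ cKO low against WT (3 called), CD23+ cKO high against WT (55), CD23+ cKO high against low (0), ABC (144) and LLPC (1). DESeq2 called 5, 138, 36, 442 and 3. Without a filter the first 4 were 14, 237, 82 and 629. Limma voom called 129 for CD23+ cKO high against WT, 238 for ABC and 2 for LLPC. With all 28 libraries in 1 fit these were 10, 94 and 9. Asking for a log2 fold change of at least 1 left 64 in ABC, by construction. For the differences between subsets, ABC minus CD23+ (0), LLPC minus CD23+ (1) and LLPC minus ABC (5), DESeq2 called 27, 53 and 41, and LLPC minus ABC rose to 8 without a filter. Apart from the 2-fold limit, the causes were not tested. In the simulated data DESeq2 made 27, 17, 23, 21 and 34 false calls in the genotype comparisons, in the order above. Its calls there numbered 207, 190, 194, 177 and 157. By the same count edgeR made 8, 9, 14, 11 and 5 false calls among 184, 182, 179, 160 and 108. For the differences between subsets DESeq2 made 11, 26 and 13, and edgeR 4, 6 and 3. Some of the further DESeq2 calls may therefore be false.

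Leaving out 1 library at a time gave 14 to 54 for CD23+ cKO high against WT, 0 to 2 for cKO high against low (2 without cKO low replicate 3), 41 to 290 for ABC and 0 to 1 for LLPC. For the differences it gave 0 to 9 (9 without LLPC WT replicate 6), 1 to 12 (12 without LLPC WT replicate 4) and 2 to 19 (19 without LLPC cKO high replicate 3). For cKO low against WT it gave 3 to 4. Alternatives chosen after seeing the data concerned the series of animal numbers of CD23+ WT replicate 6 and cKO low replicate 3. As a covariate it gave 109 for CD23+ cKO high against WT and 3 for cKO high against low. Without both libraries, cKO low against WT had 5 and cKO high against low 2.

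With the animal as a block, ABC minus CD23+ had 1 called feature and LLPC minus CD23+ 3, and no other count between subsets moved by over 1.5 times. Within a subset the replicate numbers are only numbers: the same-number correlations ran from 0.05 to 0.24 for cKO low and WT, and were under 0.1 in all other pairs but 1. With that replicate block cKO high against low had 12 called features, ABC 69 and LLPC 0, and the other 2 comparisons stayed within 1.5 times. Removal of immunoglobulin genes, protein-coding genes only, all gene list and X-linked tests, and composition without immunoglobulin were not run, as no ID could be matched to a gene. Simulated 2-fold changes were recovered least in LLPC, at 20%, and in ABC, at 68%, so small changes there can be missed.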

Other observations

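The tests of explanations in this part were chosen after the results were seen, whereas the counts over other splits of the samples were planned. The 49 features higher in CD23+ cKO high than in WT were mostly features that are higher in plasma cells than in CD23+ cells. Against the 3 CD23+ cKO low libraries, which did not enter their selection contrast, 42 of the 49 were higher in WT LLPC, compared with 2783 of 12122 features (Fisher's exact test, two-sided, p = 1.69e-20), and 18 were higher in WT ABC, compared with 763 of 12122 (p = 3.58e-10), with 16 in both. Features are not independent, so these p-values are too small, and the background was not matched to the abundance of the 49. WT ABC had fewer libraries than WT LLPC, so 42 and 18 are not directly comparable. The mean log2 CPM of the 49 was 1.58 ± 0.233 in CD23+ WT, 2.09 ± 0.236 in cKO low, 3.37 ± 0.519 in cKO high, 4.09 ± 0.508 in ABC WT and 4.5 ± 0.939 in LLPC WT (SD over libraries). It was 4.81 ± 0.0575 in ABC cKO high, above the LLPC WT mean. Within LLPC WT it was 4.63 to 5.9 in replicates 1, 3 and 6 and 3.57 to 3.87 in the others, which lay below the ABC WT mean. A high level of the 49 is thus not particular to plasma cells.

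The features that fell in ABC cKO high were largely those that are lower in plasma cells than in CD23+ cells. Of the 75, 56 were lower in WT LLPC than in WT CD23+ cells, or 74.7% against 35.8% of 12487 features (Fisher's exact test, two-sided, p = 1e-11), and of the 66 risen features that could be looked up, 35 were higher in LLPC, or 53.0% against 32.0% (p = 0.000479). Among 35 splits of the 7 ABC libraries, only the real one, 1 split, reached the 74.7% in the leading 75 fallen features, and the highest other was 68.0%. The share of the risen features was not tested over splits. Features are not independent, so the Fisher p-values are too small, and the background was not matched for abundance. As a hypothesis, ABC of cKO high animals may lie further along a path towards plasma cells. The share sets LLPC against CD23+ cells, so it cannot tell this from a move away from CD23+ cells alone. Whether the ABC sorts differed in their content of CD23+ cells was not tested. A direct score argues neither way: the 200 features most reduced in LLPC had a mean log2 CPM of 3.94 ± 0.154 in ABC cKO high and 4.33 ± 0.197 in ABC WT, a difference of -0.397 (exact two-sided permutation test, p = 0.0571, adjusted 0.114 over 4 scores, where 0.0286 is the smallest possible p), and the 200 most raised differed by -0.0704 (adjusted p = 0.869).

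Stray ABC or LLPC in the CD23+ sort are argued against as the source of the 49 higher features. With the cKO high libraries of ABC and LLPC as the source, the median share needed was 27.5% ABC RNA over 48 of the features or 40.4% LLPC RNA over 47, the rest not being higher in the source, while 32 abundant features restricted to ABC allowed a median of 0.0938% (upper quartile 0.766%) and 134 restricted to LLPC allowed 0.0508% (upper quartile 0.292%). The 49 varied together, with a mean pairwise correlation of 0.5 across 9 LLPC libraries within their groups, where the highest of 1000 random lists of like abundance reached 0.097. Part of this follows a split among WT LLPC libraries, since the mean of the 49 was 4.63 to 5.9 in replicates 1, 3 and 6 and 3.57 to 3.87 in the others, the split that called 2244 features. With those 3 libraries centred on their own the correlation was 0.408 (highest random list 0.0787). The mean of the 49 still ran from 4.63 to 5.9 within them. This centring therefore cannot tell whether that split is the only source. The random lists were matched for abundance only, whereas the 49 were chosen for a shared rise in CD23+ libraries. Passing the random lists therefore does not show shared regulation. A set of features regulated together may be involved, as may a cell type outside the 3 sorted subsets, which was not tested. The 200 features most raised in LLPC had a median log2 fold change of 0.156 and an upper quartile of 0.753 in CD23+ cKO high against WT. For the 200 most raised in ABC these were -0.00514 and 0.64. The lower quartile of the 49 was 1.42, but they were chosen for being higher in this same contrast, so that value is too large. Setting the profiles against the 49 therefore cannot decide on a wide shift towards either profile. A shift towards LLPC stays open, as the 200 features most raised in LLPC differed by 0.31 in mean log2 CPM between CD23+ cKO high and WT (exact permutation test, p = 0.0476, adjusted 0.114), and those of ABC by 0.0222 (p = 0.869, adjusted 0.869). Of the 200 of LLPC 15 were among the 49, and of those of ABC 14. These were chosen for rising in this contrast and add to both differences. In the other subsets of the same animals, which are not independent of the CD23+ libraries, the mean of the 49 differed by 0.719 in ABC (exact permutation test, p = 0.0857, adjusted 0.171 over 2 subsets, a test that could not pass after adjustment with 35 splits) and by -0.271 in LLPC (p = 0.679, adjusted 0.679).

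Other splits of the same libraries show which counts chance can give. For CD23+ cKO high against WT, 1 of 84 splits, the real one, gave 55 features and the highest other gave 1. For ABC 1 of 35 splits gave 144, with a highest other of 9. No other split came near either count, which argues against chance for both. However, 1 of 84 and 1 of 35 are the smallest shares possible here, and they were not adjusted over the comparisons. For CD23+ cKO low against WT, 6 of 84 splits gave at least 3, so chance is not excluded for that count taken alone. All 3 features were also called lower in ABC cKO high, which comes from other cKO animals and shares no libraries with this comparison, although 4 WT animals gave both. The highest other split there called 1063 features and set WT replicates 3 and 6 with cKO low replicate 3, which points to a structure of these libraries that the groups do not explain; 2 of the 3 come from the separate series of animal numbers. For LLPC 3 of 84 splits, the real one included, gave at least 1 feature. The split of WT replicates 1, 3 and 6 from the rest called 2244, and the next highest called 2. The real count of 1 lies below both, so chance is not excluded for that count taken alone. For CD23+ cKO high against low the 10 splits are too few to exclude chance, the real count being 0, that of all 10 splits at least 0, and the highest other 3.

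For the WT subsets, 100 splits were drawn for each comparison and 1, the real one, gave the count reported: 3165 for ABC and CD23+ (highest other 607), 9189 for LLPC and CD23+ (highest other 3194) and 7144 for LLPC and ABC (highest other 3858). This argues against chance as far as the drawn splits can show. Among splits that part as many same-animal pairs as the real one, the highest others were 293 of 7 splits, 3194 of 7 and 1 of 6. The remaining splits put libraries of 1 animal on the same side.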
